A study of Homo sapiens with 18 samples.

How the data were processed

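RNA was measured in neurons taken by laser microdissection from the substantia nigra pars compacta of post-mortem brains, 8 control and 10 Parkinson's disease (PD) samples, 1 array each. Per the labels, total RNA was extracted with a column kit, amplified with a whole-transcript kit, labelled with biotin and hybridised to an Affymetrix array of 54675 probe sets. The deposited values are linear signal intensities (arbitrary intensity units) that the submitters' processing notes credit to MAS5. The MAS5 version and detection calls are not given in the sources used here. On the values themselves, the mean of each array after leaving out the lowest and highest 2% was 500, and values ran from 0.163 to 3300670 with no log applied. No further normalization was applied for the results as reported. The number of arrays limits precision, and no read depth applies.

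Of the probe sets, 62 were array controls, 41097 had 1 gene in the probe table, 1801 had several genes and 11721 were not listed. The 59 probe sets of Y-linked genes, XIST and TSIX were left out of every test because they carry donor sex. Signals were transformed as log2(signal + 16). Each of 19740 genes was represented by its probe set of highest mean log2 value, and the 12195 genes at or above the median of all probe sets (7.75) were tested. Probe sets with several genes or none listed were tested apart.

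PD was compared with control by limma 3.58.1 (lmFit, eBayes with a mean trend, 2-sided) in R 4.3.3, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Of 35 gene lists fixed in advance (1066 genes, 841 of them tested), 34 had at least 5 tested members, and the blood list with 2 did not. Lists were tested by limma's camera with a preset correlation of 0.01, which compares a list with all other genes, and the tests were repeated with the correlation estimated per list and with fry, which asks whether a list's genes move one way. The size of a list shift is the mean over its members, its SE comes from the per-array list scores, and the p of those scores is from 2-sided exact permutation of the group labels. Array quality measures were compared in the same way. Interactions of group and title mark were tested by limma for genes and, for lists, by permuting group labels within the mark, with no common PD effect removed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

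The groups, tests, filters, lists and the rule for naming genes were fixed before the data were examined. The rule names the 10 genes higher and 10 lower with the largest difference among those that passed, filled up by smallest p, then up to 3 members with the smallest p from each list that passed and up to 2 members past the threshold from every other list. TH, SLC6A3, SLC18A2, DDC, ALDH1A1, NR4A2 and PPARGC1A were always named, and a further gene fixed by name was not analysed here. Applying the rule within the marked and unmarked arrays was decided after the data were examined.

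The procedure was tested on simulated data with the spread of these arrays. With all 18 arrays it recovered 0%, 28%, 76% and 84% of 50 genes shifted by 1, 2, 3 and 4 log2 units, with 10 of 11995 unchanged genes called. With the 7 marked arrays it recovered 0%, 2%, 8% and 30%, with 0 unchanged genes called. A list of genes shifted by -1 was called in both, and 0 of 20 unshifted lists were. The simulated genes were independent of each other, which the genes of these arrays are not. Few genes were changed in the simulation, whereas 4737 had an unadjusted limma p under 0.05 in the marked arrays. Recovery after adjustment depends on that share, so the rates do not describe the real marked comparison.

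Alternatives fixed in advance were pseudocounts of 1 and 64, quantile normalization, median centring, no filter, a stricter filter on low values, the mean of a gene's probe sets, every probe set on its own, only probe sets without the suffix _s_at or _x_at, no mean trend, array weights, the title mark as a block, the GAPDH 3'/5' ratio or a glial score as a covariate, and each array left out in turn. Chosen after the data were examined were the marked and the unmarked arrays alone, leaving out the 2 arrays of lowest correlation with the others, the BioB spike-in level as a covariate, and the alternatives within the marked and unmarked arrays.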

Results

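Gene expression was measured in neurons cut by laser from the substantia nigra pars compacta, the midbrain nucleus whose dopamine neurons are lost in Parkinson's disease (PD). The samples were post-mortem, 10 from PD brains and 8 from control brains, and each was hybridised to an Affymetrix oligonucleotide array with 54675 probe sets. The deposited signal intensities ran from 0.163 to 3300670 arbitrary units, and each array had a trimmed mean of 500. Of the 18 sample titles, 7 carried the letter p (3 control, 4 PD) and 11 did not (5 control, 6 PD). The labels do not give the meaning of this mark, and the comparisons of genes and lists were therefore also made within the marked and within the unmarked arrays. All differences are PD minus control on the log2(signal + 16) scale, which understates changes of dim genes, and the number of arrays limits their precision. The labels do not state that every sample came from a separate donor, so p-values measure the spread between these samples.

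Of 8 array measures, 7 differed with the title mark (adjusted p from 0.000251 to 0.0426). The median correlation with the other arrays did not pass (0.448 ± 0.0988 marked and 0.400 ± 0.150 unmarked, exact permutation p = 0.463). The probe set for 18S ribosomal RNA averaged 17.19 ± 1.05 log2 units on the marked arrays (SD, n = 7) and 13.81 ± 1.34 on the unmarked arrays (SD, n = 11), with an exact permutation p = 3.14e-05. The log2 ratio of the 3' to the 5' probe set of ACTB, a sign of RNA integrity, was 5.31 ± 0.67 and 8.08 ± 1.28 (exact permutation p = 0.000283). The BioB spike-in, a bacterial transcript added in a fixed amount, averaged 13.37 ± 1.14 on the marked and 15.02 ± 1.19 on the unmarked arrays, with an exact permutation p = 0.0099. Within the marked arrays the spike-in also separated the groups, at 12.28 ± 0.38 in controls (SD, n = 3) and 14.19 ± 0.65 in PD (SD, n = 4), with an exact permutation p = 0.0286, the smallest that 35 splits allow, and an adjusted p = 0.0571 over 8 array measures. The 18S probe set separated them too, at 16.12 ± 0.21 in controls and 17.99 ± 0.40 in PD (exact permutation p = 0.0286, adjusted p = 0.0571). In the same arrays 16.6 ± 2.47% of probe sets in controls and 4.80 ± 3.18% in PD had signals under 16. Within the unmarked arrays the spike-in was 14.88 ± 1.61 in controls and 15.13 ± 0.85 in PD (exact permutation p = 0.751). Over all 18 arrays the spike-in was 13.91 ± 1.83 in controls (SD, n = 8) and 14.76 ± 0.88 in PD (SD, n = 10), with an exact permutation p = 0.215. The median log2 signal over all 18 arrays was 7.52 ± 0.86 in controls and 8.175 ± 0.29 in PD (exact permutation p = 0.0384, adjusted p = 0.164). There, 9.07 ± 7.67% of probe sets in controls and 3.49 ± 3.09% in PD had signals under 16 (exact permutation p = 0.0532, adjusted p = 0.164). Correlations between pairs of arrays ran from 0.12 to 0.85 over the log2 signals of all 54675 probe sets, array controls included.

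**Figure D1:**
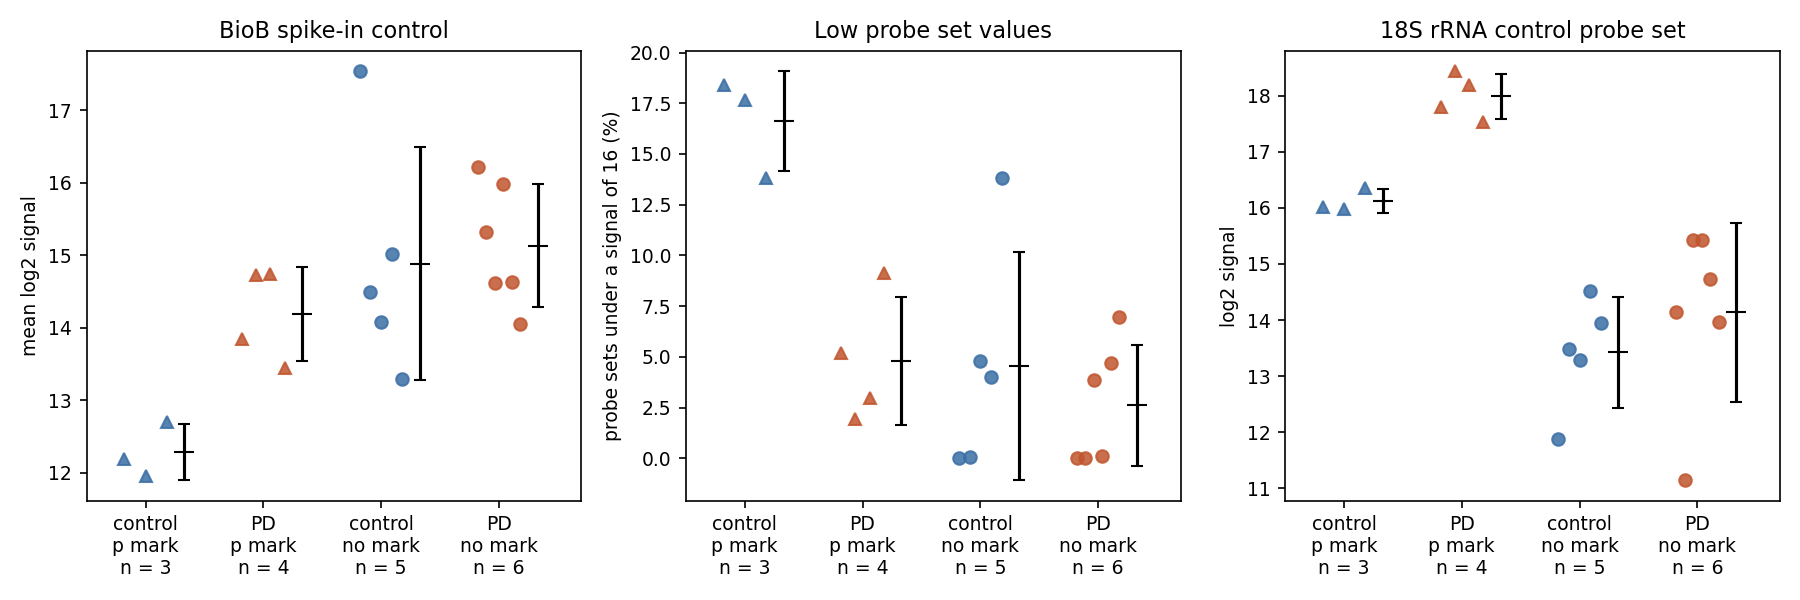
Array measures by group and title mark: the mean log2 signal of the BioB spike-in control, the percentage of probe sets with a signal under 16, and the log2 signal of the 18S rRNA control probe set. Each point is 1 array and the bars are mean ± SD; in the arrays with the p mark, controls averaged 12.28 and PD 14.19 for the spike-in, and the 2 groups did not overlap.

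The first comparison asked which genes differed between PD and control neurons over all 18 arrays. Among the genes with the smallest p, the values of UCA1, a long non-coding RNA, were higher in PD by 2.36 ± 0.55 (SE). Those of EDN2, which encodes the vasoconstrictor peptide endothelin-2, were higher by 2.31 ± 0.57, and those of BCL2L14, a member of the BCL2 family, by 2.63 ± 0.63. Values of DPYSL5, a growth cone protein, were lower by -2.66 ± 0.62, those of SH3GL3, an endophilin of endocytosis, by -1.83 ± 0.50, and those of GSTA4, which detoxifies the lipid peroxidation product 4-hydroxynonenal, by -1.91 ± 0.57. None of these passed limma's test after adjustment (adjusted p from 0.21 to 0.295, n = 8 and 10). The others of the 10 with the smallest p among higher values were LOC102724382 (2.88), MORN1 (2.71), LINC00265 (2.36), FAM238C (2.32), LINC02092 (2.53), C14orf180 (2.29) and DTYMK (2.28), and among lower values TBC1D7 (-2.32), DDX10 (-2.37), TOGARAM1 (-1.85), TMEM42 (-1.73), GTF2H5 (-1.77), NSDHL (-1.82) and GPALPP1 (-1.88).

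Of 12195 genes tested, limma called 0 higher and 0 lower in PD over all arrays, with 981 higher and 468 lower at an unadjusted p under 0.05 where chance alone gives 610. That split turned with the scaling, to 425 higher and 499 lower after quantile normalization and to 214 higher and 1463 lower after median centring, which put the median of all genes at -0.12 and -0.59, from 0.01. With array weights limma called 1446 higher and 459 lower. The weights were highest on the marked controls (1.9 to 2.23) and on the unmarked arrays PD 3, PD 9 and PD 10 (1.92 to 2.49). They were 0.283 to 1.01 on unmarked controls and 0.697 to 1.25 on marked PD arrays. That fit therefore does not separate PD well from the mark. With the mark as a block it called 2 higher, LOC102724382 by 2.91 and TNS1-AS1 by 2.87 (adjusted p = 0.0346 for both), and 0 lower; TNS1-AS1 was named after its values were seen.

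Over all arrays, genes that define dopamine neurons were not called different between PD and control neurons. TH, the rate-limiting enzyme of dopamine synthesis, averaged 7.78 ± 1.96 log2 units in controls (SD, n = 8) and 8.43 ± 1.28 in PD (SD, n = 10). Its control level lay near the median of all probe sets (7.75), which served as the filter, so a fall in TH could be understated. The dopamine transporter SLC6A3 differed by 0.39 ± 0.79, the vesicular monoamine transporter SLC18A2 by -0.03 ± 0.77, the decarboxylase DDC by 0.20 ± 0.66, the aldehyde dehydrogenase ALDH1A1 by -1.09 ± 0.83 and the transcription factor NR4A2 by -0.69 ± 0.76 (SE, adjusted p from 0.597 to 0.991). Of the 22 tested genes of the dopamine neuron list, 11 had higher and 11 lower values, the list mean was -0.12 ± 0.59 and its median 0.08, and camera did not call it (adjusted p = 0.536). With array weights, which were highest on marked controls and some unmarked PD arrays, camera called it lower (-0.52). Without control 1 or control 2 the mean was above 0 and not called (0.23 and 0.24). The list mean was -2.01 ± 1.16 in the marked and 1.05 ± 0.26 in the unmarked arrays.

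Lists of general neuronal, axonal and synaptic genes had lower mean values in PD. The neurofilament and axonal transport list was lower by -0.68 ± 0.53, with 30 of 34 genes below control, among them the neurofilament subunit NEFL (-1.96 ± 1.14), the dynein subunit DYNC1I1 (-1.43 ± 0.86) and the microtubule end-binding protein MAPRE2 (-1.47 ± 0.73). The synaptic vesicle list was lower by -0.55 ± 0.54, with 27 of 34 genes below control, such as NAPG and RIMS1, which act in vesicle fusion and its control (-1.99 and -1.55). The pan-neuronal list was lower by -0.43 ± 0.67, with 21 of 28 genes below, such as SYN2, VSNL1 and INA (-1.16, -1.37 and -1.42). Camera called the 3 lists at a preset correlation of 0.01 (adjusted p = 0.00076, 0.00361 and 0.0406), and the calls were lost with an estimated correlation (adjusted p = 0.679, 0.679 and 0.82). The axonal list was -1.71 ± 0.78 in the marked and -0.08 ± 0.55 in the unmarked arrays, the synaptic list -2.07 ± 0.89 and 0.37 ± 0.42, and the pan-neuronal list -2.25 ± 1.01 and 0.67 ± 0.51. The synaptic call ended without control 1 (-0.34), and the pan-neuronal call without control 1, 2 or 4 or PD 5, 6 or 7 (-0.35 to -0.14). Both calls were also lost after quantile normalization (adjusted p = 0.0578 and 0.511), and the pan-neuronal call after median centring (adjusted p = 0.198). The pan-neuronal call was lost too with the GAPDH, glial score or spike-in covariate, the stricter filter, the mean of probe sets, or without _s_at and _x_at probe sets (-0.45 to 0.26). So were the synaptic call with the stricter filter, the mean of probe sets or the spike-in covariate (-0.58 to -0.05) and the axonal call with the spike-in covariate (-0.09). The pan-neuronal mean was -0.67 and -0.76 without control 3 or control 7, and the synaptic mean -0.36 and -0.34 without control 2 or control 4, each still called.

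Genes of mitochondrial respiration had lower mean values in PD. Of 71 tested subunits and factors of oxidative phosphorylation (OXPHOS), 68 had lower values, and their mean was lower by -0.86 ± 0.58 (SE, n = 8 and 10). Complex I genes were lower by -0.87 ± 0.57 (31 of 32 genes), as in NDUFA10 (-1.69 ± 0.58), NDUFA13 (-1.96 ± 0.75) and NDUFB5 (-1.17 ± 0.55). Complexes II and III were lower by -0.84 ± 0.57 (10 of 10), as in UQCRQ (-1.50), the electron carrier CYCS (-1.23) and SDHD (-0.90). Complex IV was lower by -0.98 ± 0.67 (11 of 11), as in COX7B (-2.05), COX6B1 (-1.50) and COX8A (-0.97), and the ATP synthase, complex V, by -0.79 ± 0.60 (16 of 18), as in ATP5MK (-1.27), ATP5F1C (-1.44) and ATP5MJ (-1.49). Without PD 2 the complex IV mean was -0.64, still called. Camera called each of the 4 lists (adjusted p = 5.65e-06, 0.00417, 0.00284 and 0.000885), no single gene passed, also when adjusted over the list alone, and no list was called with an estimated correlation (adjusted p = 0.679 for each, and p = 0.178 by that test for the 71 genes together) or by exact permutation of the list mean (p = 0.154 for the 71 genes).

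The OXPHOS mean was -1.87 ± 0.48 in the marked arrays (n = 3 and 4) and -0.29 ± 0.61 in the unmarked arrays (n = 5 and 6). In the unmarked arrays camera called none of the lists of complex I, II and III, IV or V (adjusted p = 0.198, 0.577, 0.0855 and 0.298). It called the 71 genes together lower there (camera p = 0.00442, tested alone and so not adjusted). They were not called with an estimated correlation (p = 0.534) or after quantile normalization (p = 0.0593). That call also ended without control 6, control 8, PD 1 or PD 2 (-0.14 to 0.04), and it was kept without control 3 or 5 or PD 3 or 10 (-0.60 to -0.44). With the spike-in level as a covariate, chosen after the data were examined, the mean over all arrays went from -0.86 ± 0.58 to -0.19 ± 0.28. Camera then called the 71 genes together and complex I, and not the other 3 lists. With the glial score as a covariate the mean over all arrays was -0.89, still called. The study's paper reported on respiratory chain genes and PGC-1alpha from these samples, so these lists are not independent evidence of a direction.

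Among other mitochondrial lists, the tricarboxylic acid (TCA) cycle list was lower by -0.52 ± 0.35 (24 of 29 genes), as in PDK3 (-1.18), SUCLG1 (-1.27) and ACO1 (-1.15), and the mitochondrial ribosome list by -0.43 ± 0.35 (47 of 61), as in MRPS9 (-2.12), MRPL48 (-1.78) and MRPL9 (-1.56). Camera called both (adjusted p = 0.00361 and 0.00129), and neither with an estimated correlation (adjusted p = 0.679 for both). Without control 1 or control 2 the mitochondrial ribosome mean was -0.29 and -0.28, still called. Both calls were lost with the stricter filter (-0.55 and -0.42) and with the spike-in covariate (-0.12 and -0.03). They were -1.15 ± 0.41 and -1.19 ± 0.28 in the marked and -0.16 ± 0.39 and -0.0011 ± 0.34 in the unmarked arrays. Mitochondrial import (-0.30 ± 0.42), glycolysis (-0.11 ± 0.49) and the PGC-1alpha and mitochondrial biogenesis list (-0.10 ± 0.18, 14 genes higher and 15 lower) were not called (adjusted p = 0.0975, 0.516 and 0.531). Their means were -0.998, -0.98 and 0.12 in the marked and 0.09, 0.39 and -0.23 in the unmarked arrays. PPARGC1A, which encodes PGC-1alpha, differed by 0.22 ± 0.56.

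**Figure D2:**
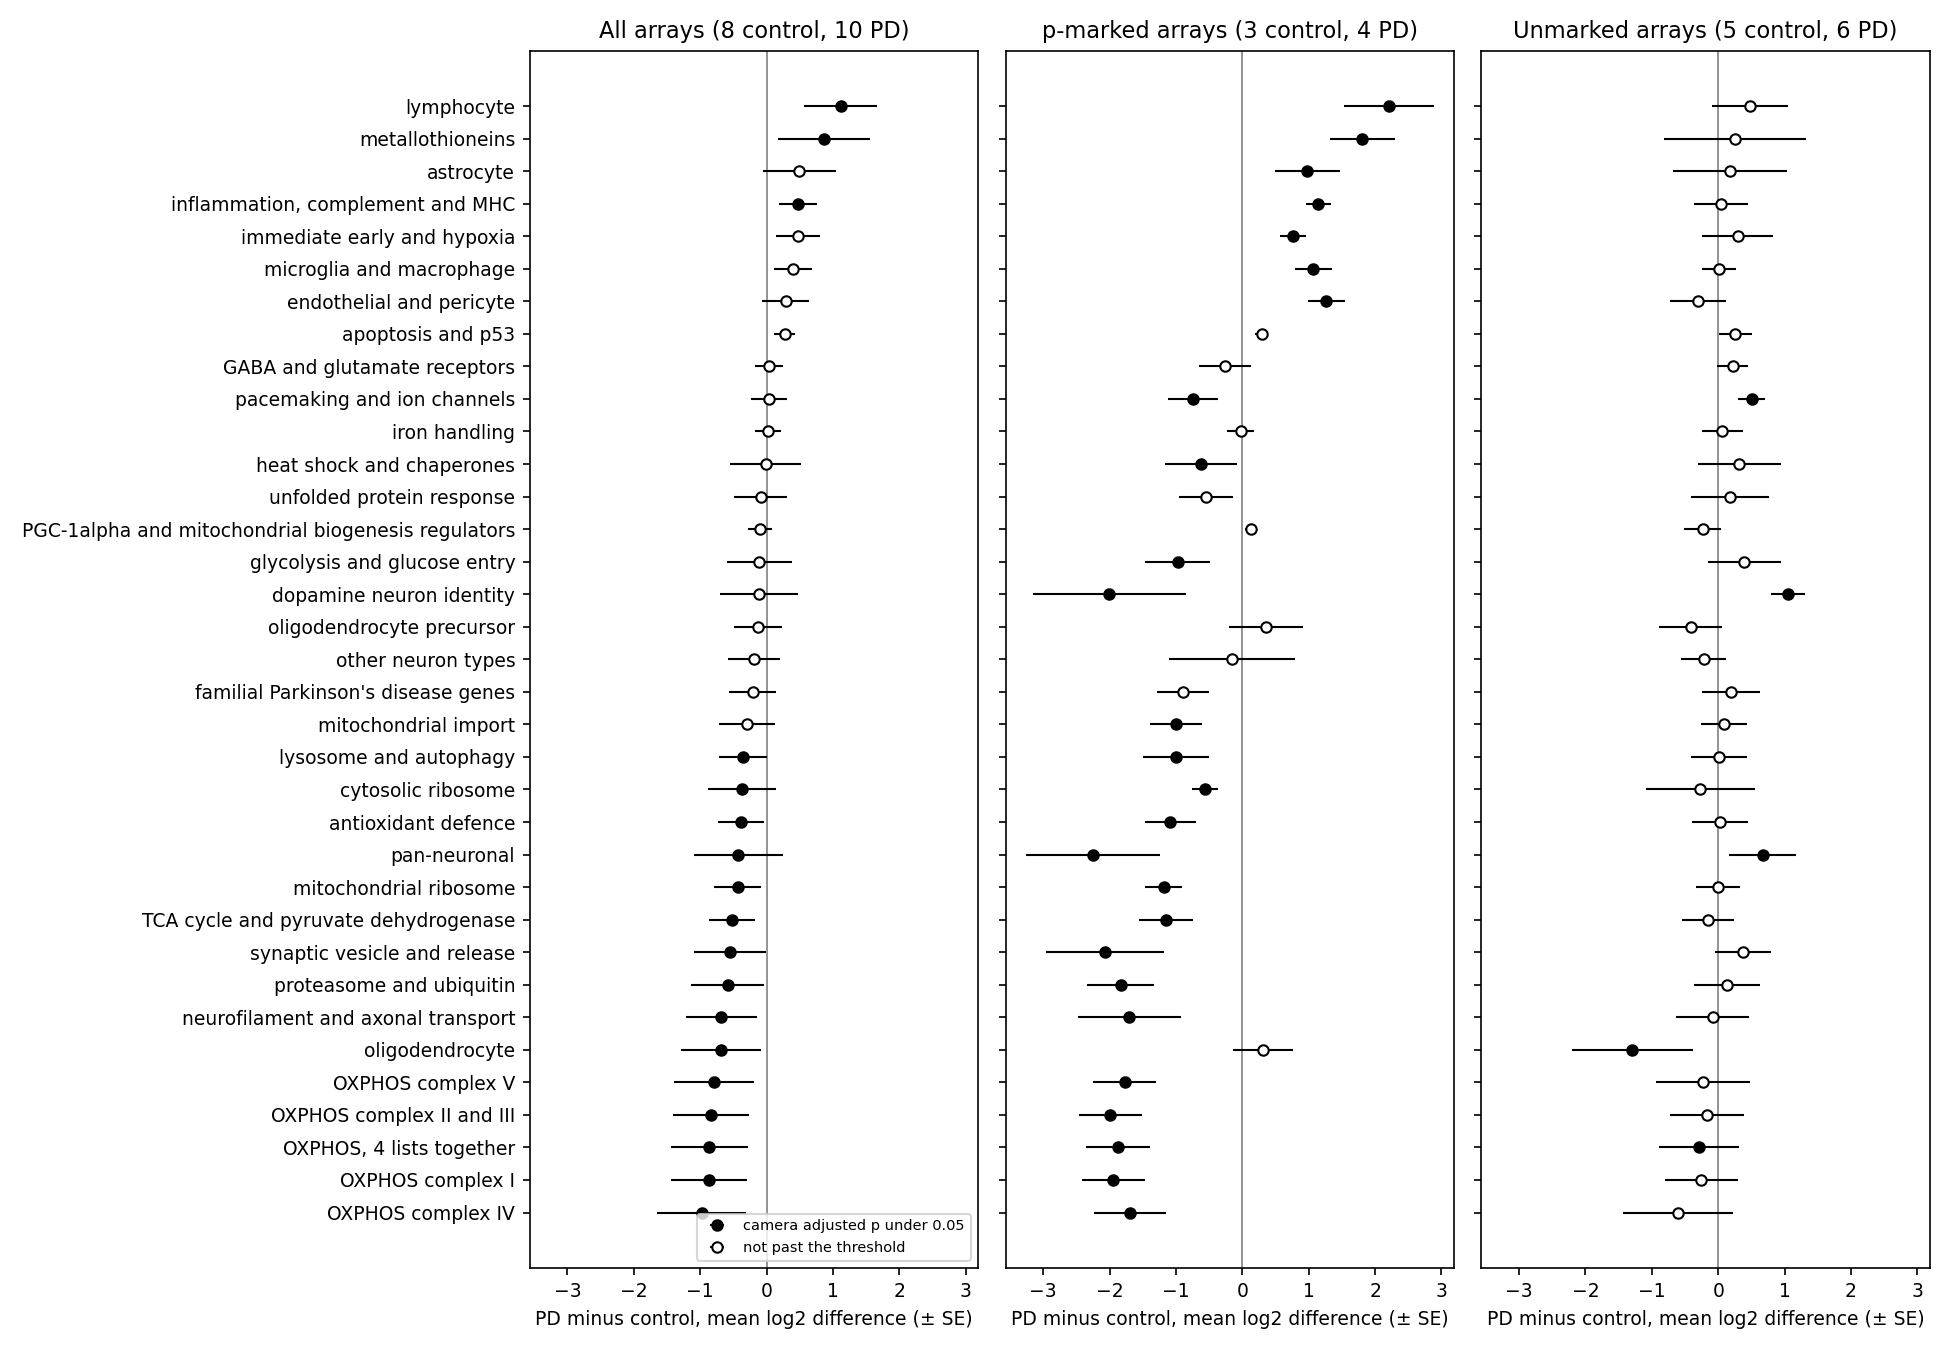
Mean difference of each gene list between PD and control (PD minus control, log2, ± SE of the list score across arrays), for all arrays, the marked arrays and the unmarked arrays. Filled points passed camera at a preset correlation of 0.01, and none of them passed with an estimated correlation; the 4 OXPHOS lists together sat at -0.86, -1.87 and -0.29 in the 3 panels.

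Protein turnover and translation genes were also lower on average over all arrays. The proteasome and ubiquitin list was lower by -0.59 ± 0.55 (30 of 37 genes), as in PSMA4, PSMD10 and PSMD8 (-1.72, -1.63 and -1.35), and the lysosome and autophagy list by -0.36 ± 0.36 (31 of 47), as in the proton pump subunits ATP6V1H and ATP6V1G2 (-2.12 and -1.36) and PPT1 (-1.29). The antioxidant list was lower by -0.38 ± 0.34 (26 of 33), as in GSTA4, the glutathione synthesis enzyme GCLC (-1.49) and catalase, CAT (-1.40), and the cytosolic ribosome list by -0.37 ± 0.51 (46 of 51), as in RPS24, RPL9 and RPS9 (-1.17, -0.98 and -1.05). Camera called the 4 lists (adjusted p = 0.00076, 0.0143, 0.0212 and 0.00556), and none with an estimated correlation (adjusted p = 0.679, 0.679, 0.679 and 0.82). Their means were -1.83, -0.999, -1.09 and -0.57 in the marked and 0.13, 0.02, 0.03 and -0.27 in the unmarked arrays. The lysosomal and antioxidant calls ended without control 1 or control 2 (-0.24 to -0.23 and -0.29 to -0.24) and with the GAPDH covariate (-0.27 and -0.33), and the ribosomal call without PD 2 (-0.11). Without other arrays the calls were kept and the means moved. They were -0.35, -0.35 and -0.38 for the proteasome list without control 1, 2 or 4, -0.59 for the antioxidant list without control 3, and -0.73, -0.20 and -0.23 for the ribosome list without control 3, 6 or 8. All 4 calls were lost after quantile normalization (adjusted p = 0.0578, 0.134, 0.109 and 0.872), where the ribosomal shift relative to all genes was 0.0061, and with the spike-in covariate (0.04, 0.04, 0.01 and 0.10). The stricter filter ended the lysosomal, antioxidant and ribosomal calls, the mean of probe sets the antioxidant and ribosomal calls, and leaving out _s_at and _x_at probe sets the lysosomal and ribosomal calls. Heat shock (-0.01 ± 0.54), unfolded protein response (-0.09 ± 0.40), iron handling (0.03 ± 0.20), apoptosis (0.27 ± 0.16) and familial Parkinson's disease genes (-0.21 ± 0.35) were not called (adjusted p from 0.288 to 0.934). In that order their means were -0.62, -0.55, -0.03, 0.29 and -0.89 in the marked and 0.32, 0.18, 0.06, 0.26 and 0.19 in the unmarked arrays. The iron list had a mean above 0 and a camera direction below 0.

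Of the lists for other cell types, camera called 2 over all arrays, oligodendrocyte and lymphocyte genes, and neither with an estimated correlation (adjusted p = 0.679 for both). The oligodendrocyte list was lower in PD by -0.69 ± 0.61, with 22 of 24 genes below control, as in EVI2A (-1.24), the galactolipid enzyme UGT8 (-1.45) and OPALIN (-1.09). Astrocyte genes differed by 0.49 ± 0.55, microglial genes by 0.40 ± 0.29, endothelial and pericyte genes by 0.29 ± 0.36 and oligodendrocyte precursor genes by -0.12 ± 0.36, none of them called (adjusted p = 0.0772, 0.25, 0.322 and 0.618). In that order their means were 0.98, 1.07, 1.26 and 0.36 in the marked and 0.18, 0.0054, -0.30 and -0.42 in the unmarked arrays. Among immune and stress lists, lymphocyte genes were higher by 1.12 ± 0.55 (5 of 5 genes), as in CD3G, CD79B and CD79A (1.58, 1.40 and 1.03). Of 17 lymphocyte genes fixed in advance, only these 5 were tested. Their mean was 7.30 ± 1.36 in controls, under the filter level of 7.75, and 8.42 ± 0.96 in PD (SD). On average they thus passed the filter through the PD arrays, and their values in controls were dim. Metallothioneins, which bind zinc and copper, were higher by 0.87 ± 0.69 (7 of 8), as in MT1M and MT1H (1.43 and 1.37), and inflammation, complement and MHC genes by 0.47 ± 0.28 (21 of 28), as in the chemokine CCL2 (1.91), the antigen transporter TAP1 (1.73) and IL1B (1.71). Camera called the oligodendrocyte, lymphocyte, metallothionein and inflammation lists (adjusted p = 0.0014, 0.0212, 0.0437 and 0.046), each lost with an estimated correlation (adjusted p = 0.679), and the immediate early and hypoxia list (0.47 ± 0.33) was not called (adjusted p = 0.0501). It was 0.76 in the marked and 0.29 in the unmarked arrays.

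The oligodendrocyte mean was 0.31 ± 0.45 in the marked and -1.29 ± 0.91 in the unmarked arrays, and the call ended without control 8 (-0.29) and with array weights (-0.15) and was kept without control 6 (-0.43). Lymphocyte genes were 2.21 ± 0.67 and 0.48 ± 0.57, metallothioneins 1.81 ± 0.49 and 0.26 ± 1.07, and inflammation genes 1.15 ± 0.19 and 0.05 ± 0.41. The lymphocyte call ended without control 1 or 2 or PD 2 or 5 (0.86 to 0.97), and the metallothionein call without any one of control 2, 3, 5 and 7 and PD 3, 4, 7, 8, 9 and 10 (0.62 to 0.92), while without PD 2 the metallothionein mean was 1.31. With the mark as a block the metallothionein and inflammation calls were lost (0.86 and 0.47), and with the GAPDH covariate the lymphocyte and metallothionein calls (0.96 and 0.68). The metallothionein call was lost too with a pseudocount of 1, without a filter or with the mean of probe sets (0.78 to 0.87). The inflammation call was lost without a filter, without _s_at and _x_at probe sets, without a mean trend, with array weights or with the glial score covariate (0.43 to 0.67). The lymphocyte score rose with the spike-in level, by 0.58 ± 0.18 per log2 unit in a model with group and mark, where the slopes of the other 33 lists lay below 0. With that level as a covariate the lymphocyte mean was 0.54 and not called. The inflammation call ended without any one of control 1, 2, 3, 4, 5 and 7 and PD 3, 4, 6, 7, 8 and 10 (0.38 to 0.46). Under median centring the means of the astrocyte and inflammation lists were -0.11 and -0.12, above the -0.59 of all genes, and the lymphocyte list could not be tested after quantile normalization. There the inflammation call was lost (adjusted p = 0.099), and the astrocyte and immediate early lists were called higher (adjusted p = 0.0024 and 0.023). Pacemaking and ion channel genes (0.04 ± 0.27), GABA and glutamate receptors (0.04 ± 0.21) and markers of other neuron types (-0.19 ± 0.39) were not called (adjusted p = 0.994, 0.994 and 0.555), and pacemaking and receptor genes had a mean above 0 and a camera direction below 0. Their means were -0.75, -0.26 and -0.15 in the marked and 0.50, 0.22 and -0.21 in the unmarked arrays.

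Within the 7 marked arrays, a comparison chosen after the data were examined, lists of neuronal and mitochondrial genes were lower in PD and lists of astrocyte, microglial, vascular and immune genes higher. No list call was kept with an estimated correlation. The genes named for the marked and unmarked arrays were chosen by the same rule after the data were examined, and the few outside it after their values were seen. The genes fixed by name were not all given there. Largest among the genes called lower were CLSTN2, a synaptic cadherin (-5.33 ± 1.30), SVOP, a synaptic vesicle protein (-5.07 ± 1.13), PNMA8A (-4.87), COPS4 (-4.80), the malate dehydrogenase MDH1 (-4.55), G3BP2 (-4.34), the ATP synthase subunit ATP5F1B (-4.31), COPG2IT1 (-4.31), JKAMP (-4.28) and NECAP1 (-4.27). Largest among those called higher were LINC00520 (5.49 ± 1.17), PPP5D1P (4.80), ABCC13 (4.74), ANKLE1 (4.65), the cytokine signalling inhibitor SOCS3 (4.60), C17orf99 (4.57), MUC6 (4.39), NR2E1 (4.34), ANKFN1 (4.31) and ELF3 (4.29). These 20 had adjusted p from 0.0273 to 0.0435 in limma (n = 3 and 4). In all, 1320 genes were called higher and 781 lower, and 2641 and 2096 had an unadjusted p under 0.05. The higher genes were dim in marked controls (median 6.81) and the lower genes bright (median 11.92), and both medians lay near 9.4 in PD (9.45 and 9.38).

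The marked-array gene calls depended on single arrays and on scaling. Limma called 0 genes in either direction after quantile normalization (1220 higher and 1685 lower at an unadjusted p under 0.05), 0 with the spike-in level as a covariate, and 0 without any one of control 1, control 2, control 4, PD 6 and PD 7, against 1024 higher and 741 lower without PD 4 and 2196 higher and 1825 lower without PD 8. Median centring gave 196 higher and 3879 lower, with the median of all genes at -1.30.

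Neuronal lists had lower means in PD in these arrays. Of 28 pan-neuronal genes 6 fell and 16 did when adjusted over the list alone, among them CHGB (-4.09 ± 0.94), VSNL1 (-3.17 ± 0.62) and GAP43 (-2.55 ± 0.66). Of 34 synaptic genes 6 fell and 1, AP2A1 (2.27), rose, with SYT11 (-1.86), SYNGR3 (-3.61) and SV2B (-4.05) among those that fell. Of 34 axonal genes 7 fell, such as MAPRE2 (-2.18), DYNC1H1 (-2.22) and KLC1 (-2.78). In the dopamine neuron list 4 of 22 fell, SLC18A2 (-3.02 ± 0.91), KLHL1 (-3.22) and PTS and GCH1 of tetrahydrobiopterin synthesis (-3.25 and -3.48), and TH (-1.07 ± 0.87) and DDC (0.29 ± 0.87) did not pass. Among the marked controls, control 4 had a dopamine neuron score of 9.01 against 11.95 and 12.05, and a score for other neuron types of 10.75 against 8.33 and 7.55. The dopamine neuron mean of -2.01 was -3.001 without control 4, -2.68 without PD 8, and -1.53 and -1.49 without control 1 or control 2. Pacemaking channel genes averaged -0.75 ± 0.38, with SCN2B (-2.22) and KCNIP4 (-2.58) lower and CACNA1D (3.21) higher. Camera called the 5 lists (adjusted p from 8.74e-07 to 0.0357), and none with an estimated correlation (adjusted p = 0.439 for the synaptic list and 0.446 for the others) or by exact permutation (adjusted p from 0.139 to 0.224). The pacemaking call ended without control 2 (-0.73), PD 6 (-0.57) or PD 7 (-0.56), after quantile normalization (adjusted p = 0.135) and after median centring (adjusted p = 0.164).

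Of the 71 OXPHOS genes 39 fell and 1, NDUFB7 (2.62), rose in the marked arrays, and 53 fell and 1 rose when adjusted over the list alone, which is not independent evidence. Examples were UQCRQ (-3.44 ± 0.55), UQCRC2 (-2.76), UQCR11 (-2.06), NDUFA1 (-2.89), NDUFAB1 (-2.71), NDUFB5 (-2.61), COX5B (-2.31), COX7A2 (-1.82), COX6B1 (-1.76), ATP5MJ (-2.73), ATP5F1C (-2.69) and ATP5MK (-2.33). The mean OXPHOS level was 12.64 ± 0.07 in marked controls (SD, n = 3) and 10.77 ± 0.82 in marked PD (SD, n = 4), with an exact permutation p = 0.0286, the smallest possible, and p = 0.105 by camera with an estimated correlation. Of the proteasome genes 17 of 37 fell, such as PSMC6 (-2.83), PSMD14 (-3.03) and PSMC1 (-2.18), and 1 rose, PSMB2 (2.29). Falls were also seen in mitochondrial ribosome genes (10 of 61), such as MRPL15, MRPL3 and MRPS23 (-2.68, -2.50 and -2.91), TCA cycle genes (9 of 29), such as IDH3B, PDK3 and SUCLA2 (-1.99, -2.58 and -2.87), and import genes (7 of 29), such as TOMM20, MTX2 and SAMM50 (-3.30, -1.97 and -2.66), where TIMM8A (3.71) and TIMM44 (1.95) rose. Smaller groups fell within the lysosome list (7 of 47), with ATP6V1B2, ATP6V1H and PPT1 (-3.56, -3.57 and -2.35) and a rise in HEXA (2.62), and the heat shock list (8 of 38), with CCT8, DNAJB9 and CCT2 (-2.65, -2.95 and -2.36) and rises in BAG2 (3.25) and HSPA1L (2.56). They also fell in the antioxidant list (5 of 33), with TXN, GSTA4, PRDX3, PRDX1 and GSTO1 (-2.78, -2.97, -2.36, -2.35 and -2.22), and the glycolysis list (3 of 29), with LDHA, PGK1 and PFKM (-2.75, -2.72 and -2.62). Of 51 cytosolic ribosome genes 1 fell, RPS24 (-1.76), beside RPL9 (-1.15) and RPL8 (-2.49), which did not pass.

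Camera called all of these lists lower at a correlation of 0.01 (adjusted p from 3.34e-10 to 0.00511), and none with an estimated correlation (adjusted p from 0.439 to 0.597). The spike-in level differed between the groups in the same arrays, and with it as a covariate camera called 1 of the 34 lists lower in place of 18 and 9 higher in place of 7. In a model of all 18 arrays with this covariate, the marked PD effect was 2.59 ± 0.76 for astrocyte, 2.03 ± 0.76 for oligodendrocyte, 3.48 ± 1.07 for metallothionein and 1.87 ± 0.37 for inflammation genes. It was -1.54 ± 0.87 for dopamine neuron, -1.17 ± 0.695 for synaptic and -1.05 ± 0.75 for pan-neuronal genes. Each lay within 2 SE of 0, so whether these shifts outlast the covariate cannot be told. The marked PD effect was -0.75 ± 0.46 for proteasome, -0.35 ± 0.55 for axonal, -0.10 ± 0.31 for antioxidant and 0.57 ± 0.62 for heat shock genes. For lysosome and cytosolic ribosome genes it was -0.016 ± 0.38 and 0.89 ± 0.71. After quantile normalization the import and heat shock calls were lost (adjusted p = 0.0914 and 0.283). The cytosolic ribosome mean was then -0.04, with a camera direction above 0 that was not called (adjusted p = 0.41). The heat shock mean of -0.62 was -0.25 without PD 6 and -0.95 without PD 8, and called in both.

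Lists of inflammation genes and of several other cell types had higher means in PD in the marked arrays, where median centring turned 5 of the 7 list means below 0. Metallothioneins were higher by 1.81 ± 0.49, with 5 of 8 genes called, MT1M (3.68), MT1E (2.03), MT1X (1.82), MT2A (1.75) and MT1H. Endothelial and pericyte genes were higher by 1.26 ± 0.28 (4 of 23 called), with CLDN5, TAGLN, CDH5 and COL1A2 at 2.82, 2.78, 2.40 and 1.97. Astrocyte genes were higher by 0.98 ± 0.49 (3 of 22), with ALDH1L1, GFAP and FAM107A at 2.80, 2.05 and 1.96, and microglial genes by 1.07 ± 0.28 (2 of 13), with ITGAM and TYROBP at 2.48 and 1.93. Inflammation genes were higher by 1.15 ± 0.19 (5 of 28), with CCL2, CD44, CHI3L1, CXCL8 and IFITM2 at 3.05, 3.07, 3.02, 2.65 and 2.38. Immediate early and hypoxia genes were higher by 0.76 ± 0.20 (4 of 25), with ZFP36, JUN, NR4A1 and IER2 at 3.45, 2.17, 2.89 and 1.91 and LDHA lower (-2.75), and lymphocyte genes by 2.21 ± 0.67 (2 of 5), with CD79B at 2.10 and GZMK at 3.26. The lymphocyte mean was 5.94 ± 0.49 in marked controls, under the filter level of 7.75, and 8.15 ± 1.06 in marked PD (SD). Camera called these 7 lists (adjusted p from 0.00152 to 0.0357), and none with an estimated correlation (adjusted p = 0.52 for astrocytes and 0.439 for the rest). The astrocyte call ended without control 2 (0.58), the microglial call without control 1, control 4 or PD 6 (1.01, 1.09 and 0.86), and the immediate early call without control 1 or PD 8 (0.71 and 0.68). The microglial call was also lost after quantile normalization (adjusted p = 0.203) and median centring (adjusted p = 0.0942), and the immediate early call after median centring (adjusted p = 0.0664). Under median centring the astrocyte, microglial, endothelial, immediate early and inflammation means lay below 0 (-0.58 to -0.08), and above the -1.30 of all genes.

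Camera did not call the remaining marked-array lists (adjusted p from 0.0531 to 0.759), and members of them passed in both directions. Fry, which does not compare a list with other genes, called 13 of the 34 lists in the marked arrays and 0 over all arrays or in the unmarked arrays. Among the 13 were the 4 OXPHOS lists (adjusted p from 0.0294 to 0.0463), and exact permutation called 0 lists (smallest adjusted p = 0.13). Fry also called the apoptosis list higher (adjusted p = 0.0294) and did not call the astrocyte list (adjusted p = 0.12). GABRG1 (2.55), GRIN1 (2.87) and GRIN2C (2.77) rose among receptors, SLC32A1 (-2.14) fell among markers of other neuron types, and the myelin gene MBP (1.76) rose among oligodendrocyte genes. Among biogenesis regulators PPARA (2.22) and MEF2D (1.77) rose and SLC25A14 (-3.16) fell. Of the familial genes SYNJ1 (-3.11), VPS35 (-2.44), CHCHD2 (-1.71) and PINK1 (-1.62) fell and PLA2G6 (2.07) rose. In the unfolded protein response XBP1 (3.49) and DDIT4 (2.23) rose and ASNS (-3.11), DNAJB9 (-2.95) and PDIA6 (-1.89) fell, and in iron handling TFR2 (3.21) and CP (2.41) rose and ISCU (-2.37) fell. Of 27 apoptosis genes 6 rose, such as the death receptor FAS (3.16) and CASP8 (3.15), and ZMAT3 (-2.25) fell; the list mean was 0.29 and its median -0.10.

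Within the 11 unmarked arrays dopamine neuron, pan-neuronal and pacemaking lists were higher and oligodendrocyte genes lower in PD. None of these 4 calls was kept with an estimated correlation (adjusted p = 0.0619, 0.998, 0.358 and 0.785). The axonal (-0.08) and synaptic lists (0.37) were not called (adjusted p = 0.609 and 0.117). The dopamine neuron score was 9.69 ± 0.35 in PD (SD, n = 6) and 8.64 ± 0.49 in controls (SD, n = 5), a difference of 1.05 ± 0.26 (SE), and 19 of 22 genes had higher values. SDC1, a cell-surface proteoglycan (3.59 ± 0.67), the vesicular transporter-like SLC10A4 (2.91 ± 0.85) and SLC18A2 (1.82 ± 0.78) were among them, with TH at 1.66 ± 0.82 and SLC6A3 at 1.80 ± 0.82. Pan-neuronal genes were higher by 0.67 ± 0.51 (23 of 28), as in GAP43, CHGA and DNM1 (1.83, 1.41 and 1.22), and pacemaking channel genes by 0.50 ± 0.20 (19 of 29), as in CACNA1G, CACNB3 and SCN8A (2.23, 1.92 and 1.85). Oligodendrocyte genes were lower by -1.29 ± 0.91 (24 of 24), as in MOBP, SOX10 and EVI2A (-2.15, -1.99 and -2.07), and by -0.74 without control 8.

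Camera called these 4 lists (adjusted p = 8.57e-07, 0.00153, 0.0142 and 2.02e-10 for the dopamine neuron, pan-neuronal, pacemaking and oligodendrocyte lists) of the 34 at a preset correlation of 0.01. The exact permutation p of the dopamine neuron score was 0.00216, the smallest that 462 splits allow, and 0.0736 after adjustment over 34 lists. Limma called 0 genes here (259 higher and 141 lower at an unadjusted p under 0.05, where chance gives 610), and 3 higher with array weights, SDC1 (3.98), SLC10A4 (4.47) and MARCHF11-DT (3.28), the last named after its values were seen. Adjusted over the list alone, 2 dopamine neuron genes passed, SDC1 and SLC10A4 (adjusted p = 0.000392 and 0.0266). Without control 7 the pan-neuronal and pacemaking calls ended (0.36 and 0.44).

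**Figure D3:**
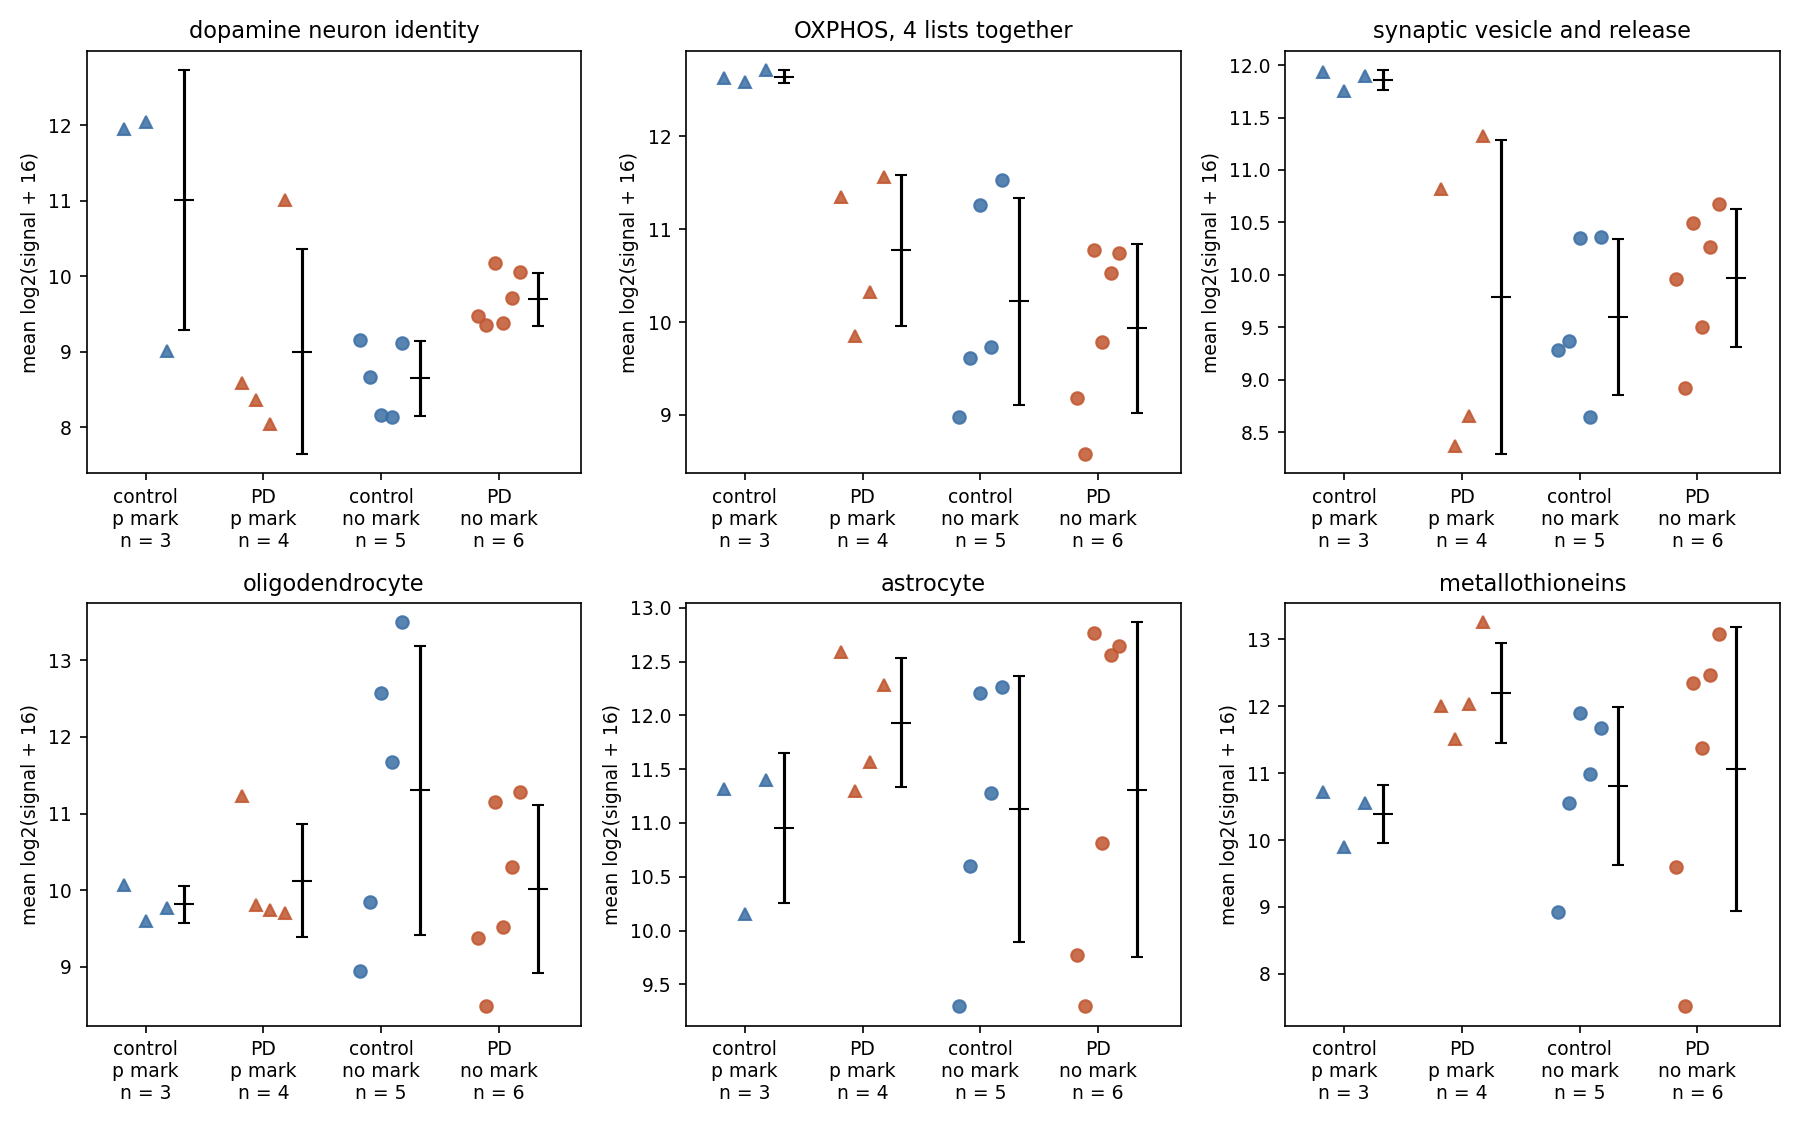
Mean log2(signal + 16) over the genes of 6 lists on each array, by group and title mark, with mean ± SD beside the points. In the unmarked arrays the 6 PD dopamine neuron scores averaged 9.69 and lay above all 5 control scores, which averaged 8.64; in the marked arrays the OXPHOS scores averaged 10.77 in PD and 12.64 in controls.

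Whether the PD difference itself depended on the mark was tested as an interaction. The permutation p of a list refers to no PD difference in either the marked or the unmarked arrays. It is not a test of equal differences alone. For the dopamine neuron list the marked minus unmarked difference was -3.05 (exact permutation p = 0.0255), for the pan-neuronal list -2.92 (exact permutation p = 0.0263), for the pacemaking list -1.25 (exact permutation p = 0.00897) and for the endothelial list 1.56 (exact permutation p = 0.0243), and each had an adjusted p = 0.223 over the lists tested, with no lower adjusted p in any list. No gene had a limma interaction past the threshold (smallest adjusted p = 0.172, with 1893 genes at an unadjusted p under 0.05 where chance gives 610). Of the 1320 genes higher in marked PD arrays, 932 (70.6%) had a difference above 0 in the unmarked arrays. Of the 781 lower genes 441 (56.5%) had one below 0. The median differences of the 2 sets in the unmarked arrays were 0.37 and -0.097. There, 53 of the 1320 and 6 of the 781 had an unadjusted limma p under 0.05 in the same direction, against 259 higher and 141 lower of all 12195 genes.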

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

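The tests of spike-in level, cell share, glial score in the marked arrays, scaled-up background and the 2 least correlated arrays, and the splits for genes over all 18 and over the 11 unmarked arrays, were chosen only after the result was seen.

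Dixon's criterion was applied to each gene, list or array measure in the 8 control and in the 10 PD arrays, marked and unmarked together. Of these 432 groups of values, 32 had 1 array far from the others, where chance gives about 22 (5%). PD 2 held 10 of them, all low, with log2 levels of 6.36 for MT1H, 9.06 for RPS24, 9.83 for RPL9, 5.48 for RPS9, 5.50 for ABCC13, 7.21 for DYNC1H1, 9.60 for MBP, 6.19 for UQCR11, 6.15 for COX7A2 and 8.56 for the complex V list. Control 3 held 6, with 7.79 for MRPL9, 6.57 for G3BP2, 6.03 for SCN2A, 8.40 for GFAP, 7.95 for COX5B and 6.14 for RPL8. These arrays also had the lowest median correlation with the others (0.183 for both). PD 5 was low for VSNL1 (6.50), EVI2A (6.08), PPT1 (6.14) and KCNIP4 (5.31), and PD 1 for CD79B (5.68), GABRG1 (6.13), MRPL15 (6.12) and ZFP36 (5.82). PD 6 was low for PSMD10 (6.48), ATP6V1G2 (5.47) and MDH1 (5.27) and high for LINC00520 (13.44). Control 2 was low for LINC00265 (6.23), PD 7 low for PSMA4 (5.78), control 8 high for DPYSL5 (11.86) and PD 10 high for NDUFB5 (11.75).

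OXPHOS genes were lower in PD in the 7 marked arrays by -1.869 ± 0.680 in a model of all 18 arrays. The shift was larger than in 10000 random sets matched on mean level over all 18 arrays (median -0.49, 2.5th percentile -0.82). OXPHOS genes thus fell further than genes of like mean level. An equal loss by brightness in the marked controls stays open, since that level was not matched. The random sets also lack the correlation between OXPHOS genes (estimated at 0.45 in these arrays). Cytosolic ribosome genes lay within their matched sets (-0.57, percentile 38.3). So did ribosome and pan-neuronal genes over all 18 arrays (percentiles 6.28 and 7.48). Less labelled target on the PD arrays stays open, because with the spike-in level as a covariate the shift was -0.6048 ± 0.516, within 2 SE of 0, as the estimate shrank by more than its SE did. A lower share of neurons in the PD samples cannot be told apart from the rest, since the endothelial and oligodendrocyte shifts differed by 0.9524 ± 0.50, under 2 SE, and glial transcripts were abundant in all groups (GLUL 14.82 in marked controls and 16.18 in marked PD, MBP 14.05 and 15.81), though not all higher in PD (TF 13.84 and 13.16, SPP1 12.64 and 11.54); the glial score as a covariate left shifts of -2.62 ± 0.31 here and -0.89 over all arrays but decides nothing, since OXPHOS scores rose with it (slope 0.95 ± 0.12) where a lower share of neurons gives a fall. A lower expression of these genes in PD neurons may also contribute and was not tested apart from these.

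At an unadjusted p under 0.05, more genes were higher (981) than lower (468) in PD over all 18 arrays. Background signal scaled up on arrays with little target is a candidate explanation, since 40.47% of the higher genes and 71.6% of the lower genes passed again after quantile normalization. The higher genes were also dim, at a median expression percentile of 29.0 against 64.2 for the lower genes. A difference between PD and control neurons stays open and was not tested apart from this.

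In the 11 unmarked arrays, oligodendrocyte genes were lower and dopamine neuron genes higher in PD. The 2 arrays with the lowest correlation to the others were argued against as the only source by a rule of 1 SE. Without them the shifts were -1.576 ± 0.818, which is within 2 SE of 0, and 1.24 ± 0.27. Without control 8 the oligodendrocyte shift was -0.74. Control 5, PD 1 and PD 5 also had few probe sets with signals under 16 (0.079%, 0.031% and 0.115%). These arrays were not left out together, so poor arrays stay open as a source. Different mixes of captured cells cannot be told apart from a change within neurons, since with group means removed the scores of the lists correlated at r = 0.1476 (permutation p = 0.659) and rho = -0.0091 (permutation p = 0.99), or r = 0.32 without the 2 farthest arrays (n = 11, 1 relation tested). MOBP, an abundant oligodendrocyte transcript, was at 14.59 in unmarked controls and 12.45 in unmarked PD, and a disease effect on neurons may also contribute.

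Chance was not excluded for the counts of lists, nor for the count of genes in the marked arrays. Over all 18 arrays, 23 of 100 splits gave as many lists as the real 17 (highest other 23). For genes the real count was 0 over all 18 arrays and in the unmarked arrays, so 100 of 100 splits in each gave as many by construction, which says nothing about chance (highest other 122 and 2166). In the marked arrays 2 of 35 splits gave as many genes as the real 2101, with 3257 in the other, and 2 of 35 as many lists as the real 25, with 25 in the other. The split with 3257 genes set PD 4, PD 6 and PD 7 against control 1, control 2, control 4 and PD 8, so it differs from the real split only in PD 8. It follows the spike-in level (13.85, 14.73 and 14.74 against 13.44 or less) and the 18S probe set (17.80 to 18.44 against 17.54 or less). It also follows the share of signals under 16 (1.92 to 5.17% against 9.11% or more). This split therefore says little about chance and does not set group apart from array level. With the spike-in level as a covariate 0 genes passed in the real split. The same held when control 1, control 2, control 4, PD 6 or PD 7 was left out, so that count is not specific to the spike-in. In the unmarked arrays 66 of 100 splits gave as many lists as the real 4 (highest other 21). The split with 2166 genes set control 3, control 5, PD 1, PD 2 and PD 5 against the rest, which follows array quality. On these arrays 0.0018 to 0.115% of probe sets had signals under 16, against 3.85 to 13.8% on the rest. Their median correlations with the other arrays were 0.183 to 0.349, against 0.375 to 0.593 on the rest.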

How the results depend on the processing

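The fits in the marked arrays alone, in the unmarked arrays alone and with the BioB spike-in level as a covariate, and all alternatives within the marked or unmarked arrays, were chosen after the data were examined, and except where the construction shows it the cause was not tested. Over all 18 arrays, limma's counts of 0 genes higher and 0 lower became 1446 and 459 with array weights, 2 and 0 with the mark as a block, and 1320 and 781 in the marked arrays. The array weights were highest on marked controls and some unmarked PD arrays. The 3 lists higher became 1 with a pseudocount of 1, without a filter, with the mark as a block or with the GAPDH covariate, 5 with a pseudocount of 64, array weights or the spike-in covariate, 0 without _s_at and _x_at probe sets, 7 in the marked arrays, and 0 to 5 with single arrays left out. The 14 lists lower became 8 after quantile normalization, 7 with the stricter filter, 1 in the unmarked arrays and 2 with the spike-in covariate. With an estimated correlation or fry, 0 lists were called higher and 0 lower, and the OXPHOS mean of -0.86 was not called; with the spike-in covariate it was called at -0.19 ± 0.28. The dopamine neuron mean of -0.12 was called at -0.52 with array weights, -2.01 in the marked and 1.05 in the unmarked arrays, and not called at 0.23 and 0.24 without control 1 or control 2 and 0.27 with the spike-in covariate. Signs reversed in the marked arrays for GAP43 (-2.55), CCT8 (-2.65) and oligodendrocyte genes (0.31). They reversed in the unmarked arrays for pan-neuronal (0.67), synaptic (0.37), proteasome (0.13) and antioxidant genes (0.034), and for pacemaking genes (0.50) only camera's direction did, as their mean over all arrays was above 0 (0.04). Signs also reversed with the spike-in covariate for pan-neuronal (0.26) and heat shock genes (0.56). In the marked arrays the 1320 genes higher and 781 lower became 0 and 0 after quantile normalization or with the spike-in covariate, 196 and 3879 with median centring, and 2312 and 1746 with array weights. With the stricter filter, which tests fewer genes, 510 were higher, and with single arrays left out the counts ran from 0 to 2196 and from 0 to 1825. There the 7 lists higher became 0 with an estimated correlation and 9 with the spike-in covariate, and the 18 lists lower 0 with it, 1 with the spike-in covariate and 6 with fry. In the unmarked arrays array weights gave 3 genes higher, 7 lists higher in place of 3 and 3 lower in place of 1. With an estimated correlation or fry 0 and 0 lists were called there, and with single arrays left out 1 to 6 and 1 to 4. Among the 173 genes named, 173 kept their side of the threshold with median centring, 172 after quantile normalization, where 1 was not tested, and 85 with array weights, where 88 came to pass. The lymphocyte list had too few members to test after quantile normalization. Signal over background limits the dim genes.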

Other observations

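No test in this part was planned beyond the counts adjusted over the list alone, and the genes HSPA6 and HEXA were chosen after their values were seen. Over all 18 arrays 5 genes were higher in PD when adjusted over the list alone. They were the inducible chaperone HSPA6 (2.91 ± 0.76, adjusted p = 0.0221), the unfolded protein response factor XBP1 (2.17 ± 0.59, adjusted p = 0.0187), the lysosomal enzyme HEXA (1.97 ± 0.53, adjusted p = 0.0362), and CASP8 (1.97 ± 0.62) and FAS (2.03 ± 0.62) of death receptor signalling (adjusted p = 0.0453 for both). Adjusted over all genes limma called 0 of the 5 (adjusted p from 0.221 to 0.302, n = 8 and 10).

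Probe sets with several genes or not listed with a gene were tested apart. Of 5834, limma called 0 in PD (smallest adjusted p = 0.0658), with 1174 higher and 79 lower at an unadjusted p under 0.05, where chance gives 292, and the median difference was 0.74.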
